A study of Mus musculus with 6 samples.

How the data were processed

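MicroRNAs were measured on 1-colour microarrays in bone marrow hematopoietic stem and progenitor cells (lineage-negative, cKit-positive) of 10-week-old female C57BL/6 mice. Per the labels, Rptor alleles flanked by loxP sites were deleted through Mx1-Cre, a recombinase switched on by interferon. Mice with Mx1-Cre (cKO, n = 3) and littermates without it (Ctrl, n = 3) each received 7 injections of 400 µg polyinosinic:polycytidylic acid, and cells were isolated 10 days after the last. Raptor, the product of Rptor, is an essential part of the kinase complex mTORC1. Per the labels' protocols, 5 µg of total RNA was reverse transcribed with biotinylated random primers, and the signal was read with a fluorescent streptavidin conjugate. The array has no probe checked here for Rptor, so the deletion itself was not measured.

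The deposited table holds 2990 probes on 6 arrays as linear relative intensity per the file header and its values. The image software, background correction and normalization of the authors are not given in the sources used here. On each array the highest value equals the 16-bit scanner limit of 65535 after multiplication by 1 constant between 829 and 987.5, and at least 99.97% of values are then whole multiples of 0.25, within a tolerance of 0.01 of that step. The authors' intensity values were therefore read as scanner intensities divided by 1 constant per array, with no background subtraction visible. The lowest scanner value was 178.5. At the limit on at least 1 array were 3 mouse probes.

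The design, fixed before the data were examined, set a floor at 1 before log2 for linear values. In the deposited units 74.6% of mouse probe values lie at or under 1, while in scanner units none do. The log2 of the deposited values was used without a floor, and the floor at 1 in the deposited units was run as an added alternative. No further normalization was applied, because equating the arrays would remove a shift shared by most miRNAs.

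The test covered 1083 probes named for mouse miRNAs, with limma 3.58.1 in R 4.3.3 (linear model, moderated variances with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Names ending in -P were read as probes of precursor regions and a star as the minor arm, which the labels do not define. On simulated data with 200 of 1083 probes changed, the test recovered 74.6% of changes of 1.5-fold, 85.1% of 2-fold and 98.5% of 3-fold, and 4.44% of its calls were false. The simulated noise was independent between probes and carried no shift shared by an array. The changes were placed at random over all probes, dim ones included, in both directions. In the real fit the SE of the log2 difference was 0.10 for the dim miR-669i and 0.34 for the bright miR-23a. These rates may therefore not hold on the real arrays, least of all for bright probes. A probe that did not pass may still have changed by 1.5- to 2-fold. The number of arrays limits the precision.

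Shifts over sets of probes were tested on each array's mean with an exact two-sided permutation test. With 3 arrays against 3, which form 10 splits, its p cannot go below 0.1. For the replicate block the sign of each within-pair difference was flipped instead, where 3 pairs allow no p below 0.25. Bright probes are the 130 whose mean log2 value exceeded 1.56, the 95th percentile of a list of muscle, liver and brain miRNAs. A few strong members raise that level, so a random-sequence level (log2 -1.29, from 38 random probes) was added after the data were seen, and 654 mouse probes exceeded it.

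The 14 lists, fixed before the data were examined, cover the let-7 family, the miR-17/92 clusters, and stem cell enriched, myeloid, erythroid, lymphoid, inflammation and interferon, p53 responsive, Drosha independent, Dlk1-Dio3 cluster, mesenchymal and stromal, epithelial, muscle, liver and brain, and platelet and megakaryocyte miRNAs. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 14 lists. A probe joined a list by the number and letter of its miRNA name, whatever its arm.

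The named probes follow a rule fixed before the data were examined. It takes up to 10 miRNAs per direction with the largest change past the threshold, filled up to 6 by the smallest p among bright probes. It adds the 3 brightest members of each list and every list member past the threshold. Probes outside the rule are said to have been chosen after their values were seen. A probe counts as above background on an array when it exceeds the 95th percentile of the random-sequence probes there. A fold is given as at least a value when all 3 arrays of 1 group, either one, lie under it; that group's values were then raised to the percentile. Where only some arrays lie under it, their number is given and the difference is not bounded. Of the 70 probes that rose, 4 have a bound and of the 4 that fell none. The bound of miR-669i is under 1, with 2 of its cKO arrays also under background, so no rise is claimed for it; 69 remain, 28 of them in the repeat family. With those bounds in place the median stays at 2.50-fold.

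The samples share replicate numbers. Deviations from the group means of same-numbered arrays correlated at 0.104, 0.124 and 0.178, each the highest among the arrays of the other group, so the numbers were taken to pair the samples. This pairing comes from the data, since the labels give littermates but not which number marks a litter. The correlations are low, and how often chance would give this order was not tested, so the paired results are tentative. Between arrays, r across mouse probes was 0.977 to 0.985 within Ctrl, 0.950 to 0.988 within cKO and 0.913 to 0.971 between the groups; probes are not independent replicates.

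Alternatives fixed before the data were examined covered 4 scalings, a filter on dim probes, the probes tested, each array left out, the replicate block, variance models, thresholds and summaries. A further 7 were added after seeing the data: scanner units, 2 corrections by the random-sequence probes, probes above their level, leaving out a repeat family, leaving out probes at the limit, and the floor at 1. Gene positions came from a RefSeq table (GRCm38.p6) and were used only for neighbours. Human-named, mismatch, random-sequence, ultraconserved-region, snoRNA and GAPDH probes stayed out of the main test.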

Results

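The arrays measured miRNAs in bone marrow stem and progenitor cells of 3 Raptor cKO mice and 3 Ctrl littermates, and the comparison asked whether loss of mTORC1 signalling alters miRNA levels. Median relative intensity over mouse probes was 0.434 to 0.481 on the cKO arrays and 0.427 to 0.474 on the Ctrl arrays. Random-sequence probes averaged 0.348 to 0.379 in cKO and 0.357 to 0.388 in Ctrl. On single arrays 58.4% to 63.8% of mouse probes in cKO and 46.4% to 52.7% in Ctrl exceeded the 95th percentile of the random-sequence probes.

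In cKO cells 70 of 1083 mouse probes rose and 4 fell. For 1 of the 70, miR-669i, a rise is not supported, because only 1 cKO array and no Ctrl array exceeds background. The probes that rose had a median change of 2.50-fold, and the largest was 7.08-fold. miR-703 rose most, from 0.574 ± 0.0898 in Ctrl to 4.58 ± 2.72 in cKO (SD, n = 3 each), a log2 difference of 2.82 ± 0.38 (SE; limma adjusted p = 0.000655). Probes of miR-466, miR-467 and miR-669, a repeat family encoded largely within the gene Sfmbt2, made up 7 of the 10 largest rises. By RefSeq positions, however, miR-466i and miR-467f lie outside Sfmbt2, and miR-466f both inside and outside it. miR-466i rose by 2.52 ± 0.31 on the log2 scale (limma adjusted p = 0.000416), and miR-467f by 2.50, miR-466f-3p by 2.32 and miR-467d* by 2.23. The -P probes of miR-669o, miR-669e and miR-467c rose by 2.30, 2.09 and 1.97, and that of miR-1187 by 2.19. miR-342-3p, known from lymphoid and myeloid cells, rose by 2.04 ± 0.32 (limma adjusted p = 0.00154).

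At an unadjusted p under 0.05, 158 probes were higher and 23 lower. The arrays of the groups did not overlap for 171 higher and 42 lower probes, 19.7% of all, where chance gives 10%. The split of calls depended on the scaling: 32 rose and 8 fell after quantile normalization, and 35 rose and 310 fell when the mean of the snoRNA and GAPDH probes was subtracted. That mean rests on 6 probes, none of them at the bright level. Calls numbered 46 without cKO replicate 2, 129 without cKO replicate 3, 34 without Ctrl replicate 1 and 48 without Ctrl replicate 3. The list counts below hold for the main run unless another setting is named. That none fell in a list is not claimed for snoRNA and GAPDH scaling.

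**Figure D1:**
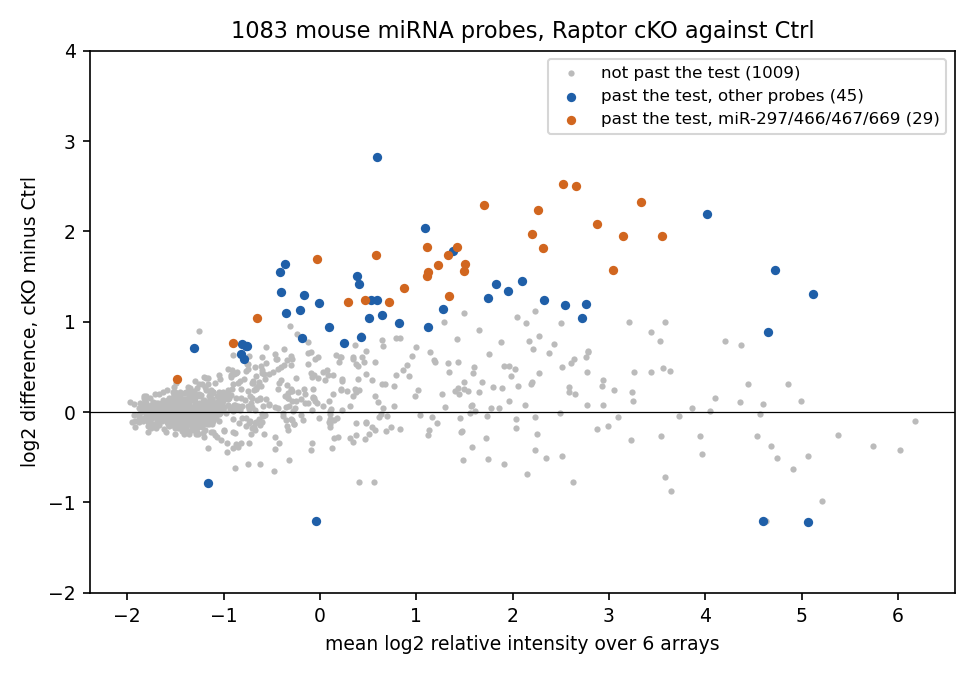
Log2 difference (cKO minus Ctrl) of each of 1083 mouse probes against its mean log2 relative intensity over 6 arrays; coloured points passed the test. Of these 70 lie above 0 and 4 below, a split that turns to 35 and 310 when snoRNA and GAPDH probes set the scale. Those are 6 probes, none of them at the bright level.

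Of 28 probes for the miR-17/92 clusters, oncogenic miRNAs active in progenitor cells, 7 rose, none fell and 21 did not pass. Of the 28, 0 passed without Ctrl replicate 1, and 1 rose without cKO replicate 2 and after quantile normalization. With snoRNA and GAPDH scaling 2 rose and 6 fell. miR-92a rose from 22.5 ± 5.57 to 55.6 ± 12.4 (SD, n = 3 each; 2.47-fold, limma adjusted p = 0.00621), with 1 cKO array at the scanner limit. miR-25 rose 2.73-fold, miR-20a 2.67-fold, miR-106a 2.37-fold, miR-17 2.36-fold, miR-20b 2.06-fold and miR-106b 1.99-fold. Human miR-17 probes with 1 or 2 mismatched bases kept 59.6% to 115% of the signal of their match. Probes for miRNAs of similar sequence, here and in other lists, may therefore share signal, and separate rises were not tested. Adjusted over the list alone, 7 rose. The list as a whole did not pass camera (adjusted p = 0.071, and adjusted p = 0.61 with an estimated correlation).

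Among 28 myeloid probes 5 rose, none fell and 23 did not pass; adjusted over the list alone 8 rose. miR-21 rose 3.12-fold, from 0.442 ± 0.0315 to 1.39 ± 0.254 (SD, n = 3 each; limma adjusted p = 0.000416), above background on 2 of 3 Ctrl arrays. miR-146a rose 2.84-fold and miR-146b 2.68-fold, both known to restrain NF-kB signalling. miR-24 rose 2.07-fold and miR-29b by 0.59 on the log2 scale; both calls were lost without cKO replicate 2, without any 1 Ctrl array and after quantile normalization, leaving 3. miR-223, an abundant myeloid miRNA, was at 27.7 ± 9.29 in cKO and 15.9 ± 0.720 in Ctrl (SD, n = 3 each; limma adjusted p = 0.165). miR-23a had a log2 difference of 0.99 ± 0.34 and miR-24-2* of 0.40 ± 0.29, neither past the test; miR-23a passed with the replicate block (limma adjusted p = 0.0475), which called 7 of the 28. The list ranked above other probes (camera adjusted p = 0.047), a call lost with an estimated correlation (adjusted p = 0.83 with an estimated correlation).

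Of 28 lymphoid probes 3 rose (miR-342-3p, miR-155 and miR-29b), none fell and 25 did not pass; adjusted over the list alone 4 rose. miR-155 rose 1.93-fold. Only miR-342-3p still passed without cKO replicate 2, without any 1 Ctrl array, and after median centring or quantile normalization. miR-26b, miR-181b and miR-181d had log2 differences of 0.89 ± 0.30, 0.84 ± 0.31 and 0.65 ± 0.29 and did not pass. The list ranked above other probes (camera adjusted p = 0.047; adjusted p = 0.61 with an estimated correlation). Of 22 inflammation and interferon probes 5 rose (miR-21, miR-146a, miR-146b, miR-155 and miR-221), none fell and 17 did not pass, also 5 adjusted over the list alone. miR-221 rose 2.21-fold; 3 of the 5 passed without cKO replicate 2 or any 1 Ctrl array, miR-155 and miR-221 being lost. miR-212 stood at 23.8 ± 4.72 in cKO and 24.2 ± 4.95 in Ctrl (SD, n = 3 each). That list did not pass (camera adjusted p = 0.124).

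Of 32 probes for stem cell enriched miRNAs 4 rose (miR-130a 2.37-fold, miR-10a 1.76-fold, miR-146a and miR-155), none fell and 28 did not pass, also 4 adjusted over the list alone (camera adjusted p = 0.867). The count was 2 without cKO replicate 2 or any 1 Ctrl array, and 1 (miR-146a) after quantile normalization. Of 16 platelet and megakaryocyte probes 3 rose (miR-130a, miR-146a and miR-10a), none fell and 13 did not pass, also 3 adjusted over the list alone (camera adjusted p = 0.685), and 1 after quantile normalization. Its mean difference was above 0 (0.23) and its median was -0.00088. Of 21 let-7 probes only that of let-7d rose (1.70-fold, limma adjusted p = 0.0367), 20 did not pass, and 1 rose adjusted over the list alone (camera adjusted p = 0.867). The let-7d call was lost in 5 of 6 runs that left out 1 array (all but cKO replicate 3) and after median centring or quantile normalization. let-7c had a log2 difference of 0.67 ± 0.25, let-7b of 0.34 ± 0.27 and let-7i of 0.07 ± 0.24, none past the test.

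**Figure D2:**
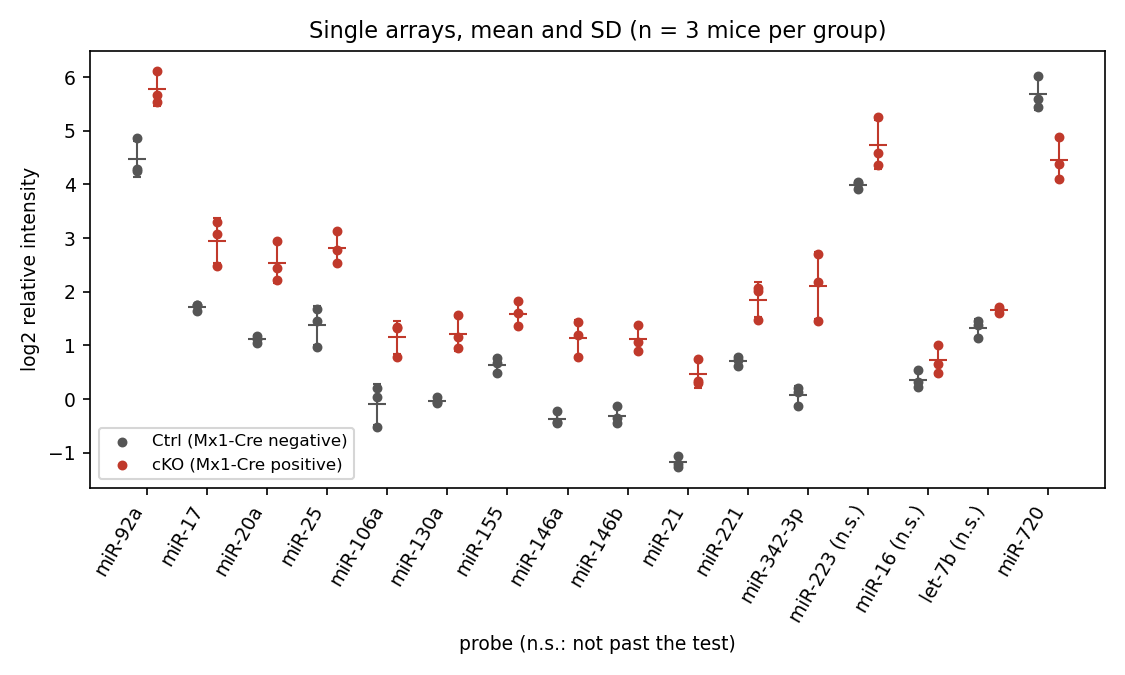
Log2 relative intensity of selected named probes on each array, with mean and SD (n = 3 mice per group); n.s. marks probes that did not pass the test. miR-92a, miR-21 and miR-146a are higher on all 3 cKO arrays than on all 3 Ctrl arrays, and miR-720 is lower.

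No probe of 15 erythroid, 27 p53 responsive, 15 Drosha independent or 17 mesenchymal and stromal probes passed limma's test, also 0 adjusted over the list alone. Of the Drosha independent probes 3 passed without cKO replicate 3 (miR-320, miR-877 and miR-1981, all higher) and miR-320 with the replicate block; of the mesenchymal probes miR-214 passed without cKO replicate 1. Camera adjusted p was 0.590, 0.566, 0.2995 and 0.587. Log2 differences were 0.36 ± 0.24 for miR-16, 0.16 ± 0.21 for miR-486 and 0.23 ± 0.18 for miR-15a. They were 0.54 ± 0.28 for miR-103 and 0.52 ± 0.29 for miR-107. For Drosha independent miRNAs the -P probes of miR-1224, miR-320 and miR-484 gave 0.04 ± 0.31, -0.04 ± 0.27 and 0.58 ± 0.31. miR-214, miR-10b and miR-199b gave 0.63 ± 0.35, 0.26 ± 0.17 and 0.09 ± 0.26. Of 15 epithelial probes that of miR-203 rose (1.66-fold, limma adjusted p = 0.0257) and 14 did not pass, also 1 adjusted over the list alone (camera adjusted p = 0.669). That of miR-203, above background on 2 of 3 Ctrl arrays, was lost without cKO replicate 2, without any 1 Ctrl array and after median centring or quantile normalization. miR-375 gave 0.43 ± 0.29 and its -P probe -0.88 ± 0.36, neither past the test.

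The 4 probes that fell were miR-720, annotated later as a transfer RNA fragment, and those of miR-1961-P, miR-1950 and miR-882-P. miR-720 fell from 52.0 ± 11.1 to 22.6 ± 6.30 (SD, n = 3 each; log2 difference -1.22 ± 0.27, limma adjusted p = 0.0117). The log2 differences were -1.20 ± 0.28 for miR-1961-P, -1.20 ± 0.32 for miR-1950, whose arrays overlapped between the groups, and -0.78 ± 0.19 for miR-882-P, above background on only 1 of 3 cKO arrays and 2 of 3 Ctrl arrays, so its size is uncertain. Each of the 4 calls was lost in 3 of the 6 runs that left out 1 array. miR-615-3p (-0.99 ± 0.30, limma adjusted p = 0.0792) and miR-2133 (-1.21 ± 0.41, limma adjusted p = 0.115) did not pass.

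Of 98 probes for the imprinted Dlk1-Dio3 cluster none rose, 1 fell (miR-882-P) and 97 did not pass, and 0 passed adjusted over the list alone. miR-494, miR-323-5p and miR-543-P had log2 differences of 0.45 ± 0.38, -0.19 ± 0.33 and -0.25 ± 0.29. Of 46 muscle, liver and brain probes none passed limma's test, including miR-290-5p at the scanner limit on all 6 arrays. Both lists ranked below other probes (camera adjusted p = 0.047 each; adjusted p = 0.83 with an estimated correlation for each). The mean difference of the Dlk1-Dio3 list was 0.0028 and its median -0.01, so its mean and its test differ in sign. The erythroid and epithelial lists had means above 0 (0.04 and 0.02) and ranked below other probes. All 14 list means fell below 0 when snoRNA and GAPDH probes set the scale, and 5 did after quantile normalization. fry, which asks whether a list moves one way on balance, passed 6 lists. They were lymphoid and inflammation (fry adjusted p = 0.00984 each), miR-17/92 (0.0256), let-7 and myeloid (0.0389 each) and platelet (0.0398). fry was run only without further scaling, so a shift shared by all probes enters these results. With direction ignored, the stem cell enriched list passed as well (fry adjusted p = 0.00145).

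Over all mouse probes the mean log2 value was 0.15 higher in cKO (exact permutation p = 0.2, n = 3 each), and the median was 0.038 higher (exact permutation p = 0.6). The 130 bright probes were 0.41 higher on average, with all 3 cKO arrays above all 3 Ctrl arrays (exact permutation p = 0.1, the smallest this design allows). Without the repeat family and miR-1187 they were 0.24 higher and the arrays overlapped (exact permutation p = 0.3). These tests are unpaired; with the samples paired by number, all 3 pairs were higher in both sets, but an exact sign-flip p cannot go below 0.25. Of the bright probes 23 rose and 2 fell. The snoRNA and GAPDH probes, which are not miRNAs, were 0.58 higher in cKO (exact permutation p = 0.1), and the random-sequence probes differed by -0.04 (exact permutation p = 0.5). Subtracting the snoRNA and GAPDH mean turned the shift of all probes to -0.42 and that of the bright probes to -0.17. Of 360 -P probes 14 rose and 2 fell, and of 723 other probes 56 rose and 2 fell.

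**Figure D3:**
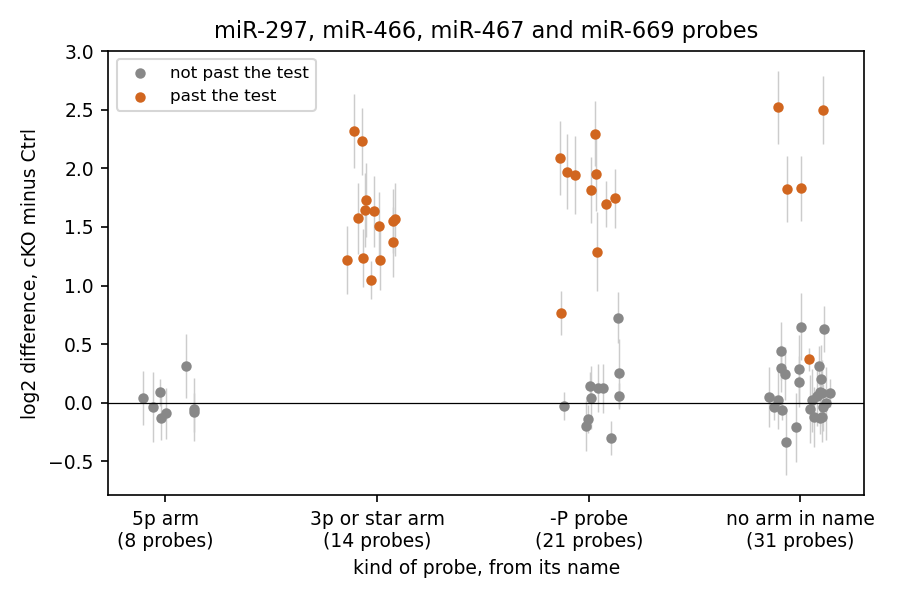
Log2 difference (cKO minus Ctrl, with SE) of each miR-297, miR-466, miR-467 and miR-669 probe, grouped by the arm in its name. All 14 probes named 3p or star passed the test, 4 after quantile normalization and 7 without Ctrl replicate 1; none of the 8 named 5p did in any of these.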

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

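The tests of scaling and of labelled RNA below were chosen after the results were seen; the count of splits and the test of a single array were set before. The scaling test was at first worded for scaling and labelling together and was narrowed after its values were seen.

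Signals appeared in probes that the comparison did not use. Among 1737 human-named probes 36 rose and 2 fell. Differences of mouse and human probes of the same name correlated at r = 0.824 across 349 pairs without -P probes, at r = 0.389 across 92 pairs of -P probes and at r = 0.785 across all 441. In all 29 pairs without -P probes whose mouse probe was called, the human probe had the same sign. Both probes of a pair carry the same miRNA name and were read on the same 6 arrays, so this agreement is not independent evidence. Human miR-466 rose by 2.26 on the log2 scale and human miR-720 fell by 0.99, both chosen after their values were seen. Among 93 mismatch probes 9 rose. Mismatch probes kept 23.8% to 48.4% of the signal of miR-21, 62.7% to 68.9% of that of miR-181a and 59.6% to 115% of that of miR-17. These are 3 of 15 sets, chosen after their values were seen: in 10 sets at least 1 mismatch probe exceeded its match, as in miR-34a (60.7% to 249%) and miR-375 (120% to 182%). Some matches in those 10 sets, such as miR-155* (0.313) and miR-181a* (0.358), lie under the random-sequence level of 0.408. Background alone could then put a mismatch probe above its match. The miR-17 match, at 5.26, lies above that level, and its mismatch probes rose too, by 1.42, 1.16 and 1.14 on the log2 scale. Among 6 snoRNA and GAPDH probes 1 rose, that of snoRNA U48R, by 1.17 (limma adjusted p = 0.0388).

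Brighter scaling of every spot, background included, is argued against as the reason why more probes rose than fell. The random-sequence probes shifted by -0.039 while all bright probes shifted by 0.41. For bright probes outside the repeat family such scaling stays open, because the gap of 0.298 is below the summed SDs of 0.329. Random-sequence probes lie near background, so a stronger bound signal alone would hardly move them, and this test cannot decide on that. A single array is argued against by 81, 45 and 124 higher calls without cKO replicates 1, 2 and 3, of which only the last was the test set before, and by 33 without Ctrl replicate 1. The snoRNA and GAPDH probes shifted by 0.58, so more labelled RNA of every kind may account for the excess. These 6 probes are a weak reference. Their group means ran from 0.37 to 1.60, under the bright level of 2.96, and 5 of them exceeded the random-sequence level. Their single shifts ran from -0.0072 to 1.17. More labelled RNA stays open as an explanation, although 2 bright probes fell and only 1 of the 6 snoRNA and GAPDH probes passed alone. The 32 ultraconserved-region probes shifted by 0.045 (exact permutation p = 0.5). Only 14 of these 32 exceed the random-sequence level, so they decide little. An effect of Raptor loss on miRNAs also stays open, untested against more labelled RNA. With 10 splits of the 6 arrays the share cannot go under 0.05: 1 split, the real one, gave 74 calls and the highest of the others gave 0, also among the splits that part all 3 pairs.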

How the results depend on the processing

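Scanner units, both corrections by random-sequence probes, the set above their level, and the runs without the repeat family, without probes at the scanner limit and with the floor at 1 were chosen after seeing the data. Of 32 named probes past the test, those tested in each alternative kept their sign: 15 among bright probes only, 24 without the repeat family, 26 without -P probes, 29 with the floor, 31 without probes at the limit and 32 elsewhere. Named probes were not followed with 1 value per miRNA name. Many lost the call: 24 kept it with median centring, 18 with quantile normalization, 19 with snoRNA and GAPDH scaling, 15 without Ctrl replicate 1 and 4 in a linear model without moderation. With the replicate block 95 probes passed (90 higher, 5 lower), 73 of them among the 74, the 4 list calls stayed and the block ended no named call. It added that of miR-23a, and with it 7 myeloid, 4 lymphoid, 6 inflammation and 1 Drosha independent probe passed as higher and 2 Dlk1-Dio3 probes as lower. Within pairs 1 to 3 the shift of all probes was 0.28, 0.070 and 0.11 and that of bright probes 0.63, 0.40 and 0.20 (exact sign-flip p = 0.25 for both, the smallest possible). On single arrays 46.4% to 63.8% of mouse probes exceeded the 95th percentile of the random-sequence probes, which limits what dim probes can show. Unless stated, the cause was not tested.

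Quantile normalization gave 40 calls (32 higher, 8 lower; 36 among the 74) and 0 lists. It sets the mean shift to about 0 by construction (-1.5e-05), and the bright shift was -0.038. Camera's direction turned for the let-7 list (mean -0.011) and the epithelial list (-0.050). Means below 0 numbered 5 of 14, against 1 without it; the others were -0.084 for erythroid, -0.085 for Dlk1-Dio3 and -0.11 for muscle, liver and brain, below 0 before. Differences of single probes turned to -0.19 for let-7b, -0.43 for let-7i, -0.13 for miR-24-2*, -0.10 for miR-16, -0.13 for miR-486, -0.011 for miR-103, -0.34 for miR-1224-P, -0.029 for miR-494, -0.11 for miR-199b, -0.027 for miR-375 and 0.0045 for miR-290-5p, which is at the scanner limit on all 6 arrays, so its sign carries no information.

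Subtracting the snoRNA and GAPDH mean lowers every cKO minus Ctrl difference by 0.58 and gave 345 calls (35 higher, 310 lower; 39 among the 74), shifts of -0.42 (all) and -0.17 (bright) and 2 lists. All 14 list means fell below 0, from -0.62 to -0.20, with -0.21 for both miR-17/92 and myeloid and -0.22 for lymphoid. Camera's direction, which ranks a list against other probes, turned only for let-7 (-0.43), p53 responsive (-0.44) and mesenchymal and stromal (-0.42). Differences of single probes turned to -0.24 for let-7b, -0.51 for let-7i, -0.17 for miR-24-2*, -0.22 for miR-16, -0.41 for miR-486, -0.35 for miR-15a, -0.032 for miR-103, -0.057 for miR-107, -0.53 for miR-1224-P, -0.12 for miR-494, -0.32 for miR-10b, -0.49 for miR-199b and -0.15 for miR-375.

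Bright probes alone gave 30 calls (28 higher, 2 lower) and 1 list, with fewer probes tested. Lower calls numbered 2 with 1 value per miRNA name, without -P probes, without a variance trend and in scanner units, and 0 with the random-sequence mean subtracted before log2. Array weights gave 183 calls (169 higher, 14 lower), an unadjusted p 181 (158 higher, 23 lower) and no moderation 6 (6 higher, 0 lower). Leaving out the repeat family, and miR-1187 with it in every such run, gave 31 calls (28 higher), all among the 44 of the 74 still tested. Lists past the test numbered 0 with median centring, tissue list centring, an estimated correlation, scanner units and random-sequence centring, 2 above the random-sequence level and 1 with the floor at 1. That floor gave 79 calls (76 higher, 3 lower), 60 of them among the 65 still tested.

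The shift of all probes was 0.15 in the main run (exact permutation p = 0.2). With the median in place of the mean it was 0.038 (exact permutation p = 0.6). It was 0.25 in scanner units and 0.24 with the random-sequence mean subtracted before log2. Above the random-sequence level it was 0.25, and with the floor at 1 it was 0.36. In each setting after the median the exact permutation p = 0.1, the smallest possible. The shift of bright probes, 0.41 in the main run, was 0.69 with the median and 0.24 without the repeat family and miR-1187 (exact permutation p = 0.3).

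miR-212 turned to 0.020 with tissue list centring, 0.081 in scanner units and 0.017 with random-sequence centring, and miR-320-P to 0.061 in scanner units. Camera's direction turned for the epithelial list with human-named probes added (mean 0.074), the stem cell list with the random-sequence mean subtracted before log2 (0.21) and above that level (0.25), and the Drosha independent list with the floor at 1 (0.20).

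Leaving out 1 array at a time gave 34 (without Ctrl replicate 1) to 129 calls (without cKO replicate 3), 33 to 124 higher, 1 to 6 lower and 0 to 5 lists. In all 6 runs 19 of the 29 called probes of the repeat family and 13 of the other 45 passed. Calls in the miR-17/92 list, 7 with all arrays, ranged from 0 (without Ctrl replicate 1) to 7, lymphoid from 1 to 4, stem cell from 2 to 4, let-7 from 0 to 2, myeloid and inflammation from 3 to 6, platelet from 2 to 3, epithelial and mesenchymal from 0 to 1 and Drosha independent from 0 to 3. Without cKO replicate 1 the named probes of miR-615-3p, miR-2133, miR-23a, miR-26b and miR-214 passed as well. In the repeat family 19 (without Ctrl replicate 1) to 30 probes rose, and 16 did after quantile normalization; 7 to 14 and 4 of these were 3p or star probes. The call of miR-669i was lost in all 6 runs. Camera's direction turned for the let-7 list without cKO replicate 2 (mean 0.13 to 0.18 over the runs) and the stem cell list without cKO replicate 3 (0.12 to 0.19). List means crossed 0 for erythroid (-0.015 to 0.070), Dlk1-Dio3 (-0.060 to 0.068), epithelial (-0.017 to 0.075) and muscle, liver and brain (-0.097 to 0.026). Ranges for single probes were -0.18 to 0.13 for miR-212, -0.21 to 0.28 for miR-1224-P, -0.18 to 0.033 for miR-320-P, -0.47 to 0.10 for miR-543-P, -0.44 to 0.091 for miR-323-5p and -0.19 to 0.34 for miR-199b.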

Other observations

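All tests of the repeat family, and the differences with the random-sequence mean subtracted, were chosen after the results were seen. The comparisons of mature with -P and star probes were set before. Their filter, which leaves out this family, miR-1187 and probes under the random-sequence level, uses choices made after the data were seen.

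Several called miRNAs belong to no list, and those named here were chosen after their values were seen. Of 11 miR-30 probes 4 rose and none fell: miR-30b by 1.55 ± 0.25, miR-30c by 1.33 ± 0.20, miR-30d by 1.08 ± 0.25 and miR-30a by 0.84 ± 0.22 (log2 difference, SE). miR-30e and the star probes of this group did not pass, with a log2 difference of -0.01 for miR-30e. miR-92b rose by 1.58 ± 0.29, miR-32 by 1.34 ± 0.28, miR-130b by 1.30 ± 0.20, miR-340-5p by 0.94 ± 0.21 and miR-421 by 0.73 ± 0.19. Left out 1 at a time, the arrays ended no call of miR-30b, miR-30c, miR-92b or miR-130b, but those of miR-30a (in 4 of 6 runs), miR-30d, miR-32, miR-340-5p and miR-421 (3 each) and miR-425 (1). Quantile normalization also ended the calls of miR-30a, miR-30d, miR-32, miR-340-5p and miR-421. miR-30b was above background on 2 of 3 Ctrl arrays and miR-421 on 1. miR-425 rose at least 1.67-fold (limma adjusted p = 0.00503), with each Ctrl array under the 95th percentile of its own random-sequence probes.

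Of 74 miR-297, miR-466, miR-467 and miR-669 probes 29 rose, against 41 of 1009 others, the 29 including miR-669i, above background on 1 of 6 arrays (Fisher's exact two-sided p = 2.79e-18, on a family picked after its values were seen and with probes that are not independent). Of 17 genomic clusters of miRNA genes that within Sfmbt2 had camera adjusted p = 4.0e-08, but adjusted p = 0.63 with an estimated correlation. All 14 probes named 3p or star rose (mean 1.56), as did 10 of 21 -P probes and 5 of 31 probes with no arm in the name. After quantile normalization 16 of the 74 rose, 4 of them 3p or star probes, and without Ctrl replicate 1 19 rose, 7 of them 3p or star probes; no 5p probe passed in either. With snoRNA and GAPDH probes setting the scale each shift of this family is 0.58 lower, so those of the 5p probes, of the 31 probes with no arm in the name (0.37) and of the 11 probes outside Sfmbt2 (0.56) fall below 0. Those of 3p and star, of -P and of the hand-picked CA-rich probes stay above it.

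In this family a rise of both hairpin arms is argued against by the 5p probes, whose mean shift was 0.0044 beside 1.56 for 3p and star probes. Binding of other RNA with a shared CA-rich sequence may explain the rise: 4 such probes of genes outside Sfmbt2 shifted by 1.98, but they were picked by hand after their values were seen, so this decides nothing, and all 11 family probes outside Sfmbt2 shifted by 0.56. Cross-hybridisation of UG-rich probes stays open as well. The miR-1187, miR-574-5p and human miR-297 probes shifted by 0.13 on average (0.23, 0.16 and 0.01). With the miR-1187 -P probe (2.19) added the average was 0.65. No probe sequences were at hand, so the CA-rich and UG-rich classes rest on recalled sequences and neither test can decide. A common shift of bright probes stays open for the family as a whole, which exceeded other bright probes by 0.44 on average and by over 0.3 in 4 of 9 pairs of arrays; its bright members did so in 9 of 9. A biological rise of these miRNAs stays open as well.

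If precursors were processed more in cKO, mature probes would gain on -P probes of the same miRNA. Only probes above the random-sequence level were compared, and the repeat family and miR-1187 were left out. In that family the -P probes shifted more (0.87) than those with no arm in the name (0.37), against this direction. Over the remaining 137 miRNAs the mature minus -P difference was 0.15 higher in cKO (exact permutation p = 0.2). The groups overlapped, but only from 0.239 (lowest cKO) to 0.244 (highest Ctrl), less than the SD of 0.101. By the rule set beforehand any overlap counts against more processing. An allowance for the SD was added after the overlap was seen, and with it more processing cannot be told apart from none. With the random-sequence mean subtracted, a choice made after that overlap was seen, the difference was 0.21 and the groups did not overlap (exact permutation p = 0.1). Under the same filter, over 35 miRNAs, the mature minus star difference was 0.42 higher in cKO with no overlap (exact permutation p = 0.1, the smallest possible). With the subtraction it was 0.70. Outside the repeat family a change of the named arm beyond its star arm may therefore be present. Star probes are dimmer, however, and background could compress their changes. Inside that family 3p and star probes shifted by 1.56 and those with no arm in the name by 0.37, the other way.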
